A study of Arabidopsis thaliana with 18 samples.

How the data were processed

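Developing seeds of Arabidopsis thaliana were profiled by RNA sequencing in 2 genotypes, wild type (WT) and dgat1-1, a mutant line named for DGAT1, a gene for the enzyme that adds the last acyl chain in triacylglycerol synthesis. Seeds were taken at 8, 12 and 16 days after flowering (DAF), and each of the 6 groups had 3 libraries, which the labels call biological replicates. Per the labels' protocols, plants grew at 23 C under 16 h of light and 8 h of dark, RNA came from the pooled seeds of 30 to 40 siliques, and stranded libraries of polyadenylated RNA were read on a HiSeq 2500 as 100 bp pairs. The hour of harvest and the position of the mutant lesion were not given in the sources used here.

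Per the labels' protocols, the authors trimmed the reads and mapped them to the Arabidopsis genome with the Araport 11 annotation in CLC Genomics Workbench 7.5.1. Counting settings, including whether strand was used and how reads of near-identical genes were shared, were not given in the sources used here. The deposited table held 37109 features, of which 4931 were listed at 0 in all 18 libraries, and gave the authors' RPKM (reads scaled to the length of the gene model and to all mapped reads) for each library, per the file headers. Its further columns, per the file headers, were the authors' mean RPKM of each group, a signed fold change of dgat1-1 against WT from a test called EDGE, used here as a score that is linear and negative for a fall, and that test's p-value. The settings of that test, and whether its p-values are adjusted, were not given in the sources used here. The means recomputed from the libraries differed from the authors' mean RPKM by at most 0.0077. Gene coordinates, types and symbols came from the Araport 11 annotation deposited with the series, in which 36962 of the features were found and 147 were not; 10 of the features lie on ribosomal DNA (rDNA). No column of another series was present (0 columns).

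Sequencing depth was recovered from the steps of low RPKM values, since 1 read is worth a fixed amount for a gene of known exon length. Among 269 to 1147 values below 0.0095 RPKM per library, 98.77% to 100% came out as whole reads within 0.05 read. The depths found in this way ran from 50.1 to 105.8 M reads with a median of 61.9 M, and the deepest was dgat1-1 16 DAF library b. At these depths the values of DGAT1, at 11.8 to 41.2 RPKM, rested on an estimated 1627 to 6073 reads per library. RPKM divides by all mapped reads, rDNA included, and the share of reads on the 10 rDNA loci ran from 19.9% to 37.9% among libraries, so RPKM of every other gene moves when that share does.

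Tests were run on log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, in 1 linear model of the 6 groups over all 18 libraries (12 residual degrees of freedom) with empirical Bayes moderation and a variance trend. The 18906 genes with an RPKM of at least 1 in at least 3 libraries were tested. All tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. The comparisons were dgat1-1 against WT at each stage, their average, their difference between stages (a moderated F test of the interaction, with each pair of stages tested as well), and successive stages within each genotype. Fold changes are on the log2(RPKM + 1) scale, which understates the change of genes at low levels. The genotype comparisons of different stages share no libraries.

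Before the data were examined, 23 gene lists with 445 memberships were fixed, all of them present in the table. They cover triacylglycerol assembly, plastid fatty acid synthesis, oil body proteins, storage proteins, late embryogenesis and dormancy, seed maturation regulators, oil breakdown, photosynthesis, starch synthesis and breakdown, sucrose use, low-sugar response, abscisic acid, jasmonate, the unfolded protein response, heat shock proteins, cell division, galactolipids, suberin with cutin and wax, and markers of seed coat (flavonoids, mucilage), endosperm and silique wall. For each list the called members were counted over all genes and again with p adjusted over the list alone. Camera in limma compared each list with all other genes in the 3 genotype comparisons at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 69 tests, and was repeated with a correlation estimated from the residuals. Of 33 calls, 2 held with an estimated correlation: jasmonate at 8 DAF and late embryogenesis at 16 DAF. A position on the WT developmental axis was the slope, across genes, of the genotype effect at a stage on the WT change between the other 2 stages, with the SD over the 3 dgat1-1 libraries and an exact permutation test.

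Genes were named by a rule written before the data were examined. DGAT1 and 16 further genes of oil and seed maturation were named whatever their result. For each genotype comparison the rule took the 8 largest rises and 8 largest falls among called genes whose groups did not overlap and whose higher group had a mean RPKM of at least 5, and up to 3 members of each list with the smallest adjusted p. It also took the 5 largest rises and falls of each WT stage comparison and the 6 smallest interaction p among genes with a mean RPKM of at least 5. Members that repeat the same finding were left out, and so were some of the largest rises and falls. The genes named are thus only part of those the rule took. Genes outside the rule are said to be chosen after their values were seen.

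The steps were tested on simulated data made from the real groups before use. In the 16 DAF comparison over 18906 genes, 39 of 50 genes planted at a log2 change of 0.5, 37 of 50 at -0.5, 49 of 50 at 1 and 50 of 50 at 2 were called, with 6 unchanged genes among 181 calls. The interaction gave 152 calls, 14 of them on unchanged genes, and the 8 DAF comparison, with no planted change, gave 0. An axis slope planted at -0.05 at 12 DAF came back as -0.0489. In the set test at 12 DAF the 1 shifted set was called and none of the others. The simulated genes were independent of each other, so this could not show false calls of lists whose members are correlated. In the real data a division of the 12 DAF libraries other than by genotype called 704 genes. The false calls counted in the simulation may therefore not carry over to the real comparisons.

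Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter on low values, a mean RPKM of at least 5, median-of-ratios scaling over 12684 genes, rescaling without the top 100 genes, quantile normalization, no variance trend, voom on the recovered reads, a model of only the 2 groups compared, and leaving out each library. Rescaling to reads outside the rDNA loci was added after the data were seen. The replicate numbers of the labels could not be matched to the table's columns, which carry letters, so a block on the letter was added in place of one on the number. Tables and plots were made with python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Isoforms, splicing and raw reads were not analysed here.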

Results

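The series compared the transcripts of developing seeds between WT and dgat1-1 at 8, 12 and 16 DAF, with 3 libraries in each of the 6 groups. Values are the authors' RPKM, given as mean ± SD over the 3 libraries of a group (n = 3) unless stated. Differences are dgat1-1 minus WT on the log2(RPKM + 1) scale. Mean depth at 8 DAF was 64.8 ± 6.14 M reads in WT and 62.6 ± 1.38 M in dgat1-1. It was 67.9 ± 3.57 M and 55.8 ± 2.98 M at 12 DAF, and 61.8 ± 2.09 M and 72.3 ± 29.6 M at 16 DAF. The adjusted p-values measure the spread among these libraries, each made from pooled seeds, and the labels do not say whether the pools came from separate sowings. The first principal component held 75.0% of the variance and separated the stages, and the second held 19.1%. Reads on rDNA took 37.5% ± 0.35 of the depth in WT and 35.0% ± 0.85 in dgat1-1 at 8 DAF. The shares were 27.2% ± 5.73 and 25.6% ± 3.90 at 12 DAF, and 22.6% ± 3.26 and 31.8% ± 1.39 at 16 DAF.

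**Figure D1:**
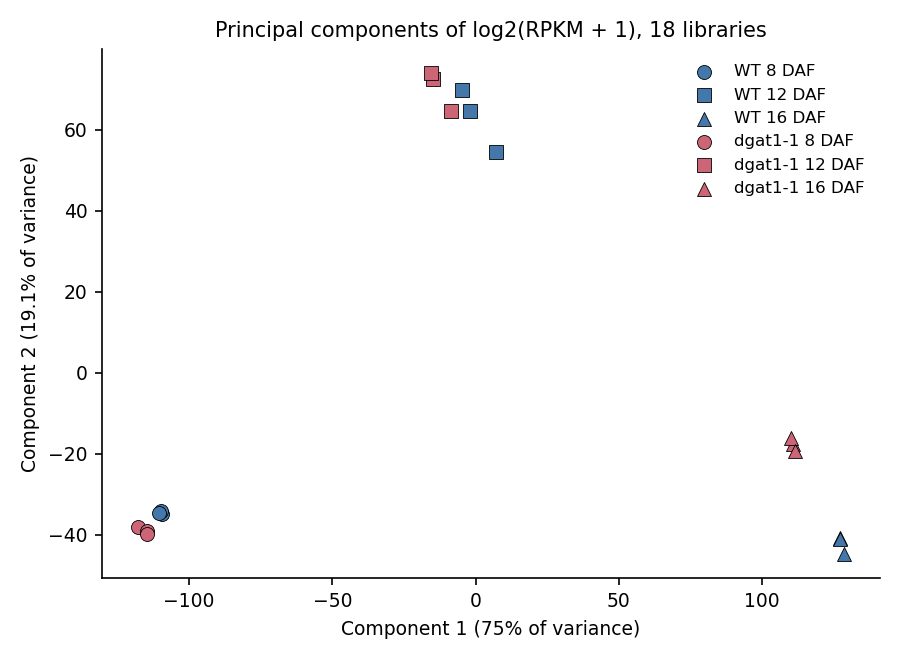
Each point is 1 of the 18 libraries, placed by its score on the first (75.0% of variance) and second (19.1%) principal component of log2(RPKM + 1), with colour for genotype and shape for stage. Libraries group by stage, and the genotypes lie farthest apart at 16 DAF.

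DGAT1 (AT2G19450, chromosome 2, 8426117 to 8429853, Araport 11), the gene the mutant is named for, was not reduced at any stage. At 8 DAF its RPKM was 11.8, 12.3 and 12.5 in WT libraries a, b and c and 13.7, 12.4 and 13.6 in those of dgat1-1. At 12 DAF it was 28.96, 22.6 and 29.8 in WT and 36.2, 41.2 and 35.0 in dgat1-1. At 16 DAF it was 20.6, 20.4 and 19.5 in WT and 23.8, 25.2 and 24.2 in dgat1-1. The difference was 0.11 at 8 DAF (limma, Benjamini-Hochberg adjusted p = 0.695), 0.46 at 12 DAF (adjusted p = 0.000801) and 0.26 at 16 DAF (adjusted p = 0.0193). The call at 12 DAF ended with only the 2 groups in the model (limma, Benjamini-Hochberg adjusted p = 0.0804, from 2.41e-05 to 0.0804 over the alternatives). That at 16 DAF ended without WT library c or dgat1-1 library b (adjusted p from 3.7e-06 to 0.0652 over the alternatives). The lesion is not given in the labels, so a transcript level neither checks nor contradicts them.

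**Figure D2:**
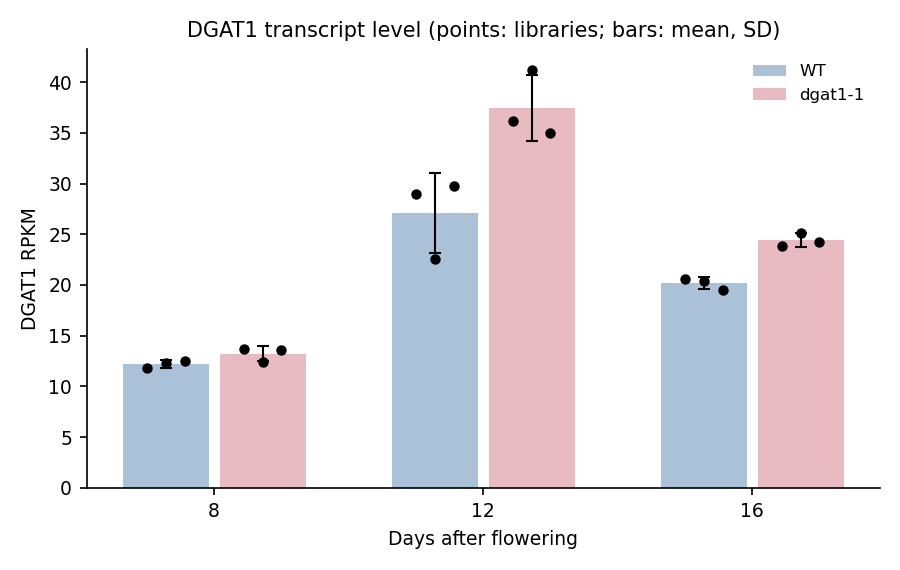
DGAT1 RPKM (vertical axis) by days after flowering, with bars for the mean of 3 libraries, error bars for the SD and points for libraries. Means in dgat1-1 were 13.2, 37.5 and 24.4 against 12.2, 27.1 and 20.2 in WT.

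The WT libraries set the developmental background. Between 8 and 12 DAF all 13 tested storage protein genes rose, with a median log2 change of 9.32. So did 17 of 19 oil body genes (median 4.32) and 17 of 23 late embryogenesis genes (median 2.21). CRA1 (AT5G44120), a 12S globulin, went from 5.55 ± 1.42 to 5249 ± 385 RPKM. SESA2 (AT4G27150), a 2S albumin, went from 15.2 ± 5.0 to 17710 ± 824 and SESA3 (AT4G27160) from 35.3 ± 12.0 to 28996 ± 1382. AT1G62220 had the largest rise, from 1.25 ± 0.35 to 2934 ± 187. The beta-glucanase BG3 (AT3G57240) was among the 5 largest falls, from 340 ± 3.48 to 1.39 ± 0.44. Photosynthesis genes (41 of 45 higher, 3 lower, median 1.00) and plastid fatty acid synthesis (34 of 37 higher, 3 lower, median 0.84) rose as well. Cell division (24 of 26 lower, 0 higher, median -0.98) and seed coat flavonoids (14 of 17 lower, 3 higher, median -1.97) fell. Endosperm markers (7 of 8 lower, 1 higher, median -1.04) and silique wall markers (4 of 4 lower) fell too. In all 12476 of 18906 genes were called, 4906 higher and 7570 lower. The counts adjusted over the list alone were the same for all of these lists. With rescaling to reads outside the rDNA loci the median of all genes went from -0.12 to -0.30 and the higher share from 39.3% to 26.7%. With a mean RPKM of at least 5 the count was 7539.

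Between 12 and 16 DAF in WT all 23 late embryogenesis genes rose, with a median log2 change of 3.45. EM1 (AT3G51810), an embryo desiccation protein, went from 0.15 ± 0.12 to 188 ± 15.1 RPKM. AT1G54870 went from 0.10 ± 0.13 to 493 ± 32.6 and BGLU19 (AT3G21370) from 0.12 ± 0.06 to 294 ± 19.6. FACT (AT5G63560), a fatty alcohol caffeoyl transferase, went from 0.44 ± 0.23 to 452 ± 22.9. Of 21 genes of suberin, cutin and wax, 17 were higher and 4 lower (median 1.87). Storage proteins (12 of 13 higher, 0 lower, median 1.63) and oil bodies (15 of 19 higher, 3 lower, median 1.18) went on rising. All 45 photosynthesis genes (median -2.82), 36 of 37 genes of fatty acid synthesis (median -1.76) and all 26 of cell division (median -2.88) fell. MLP28 (AT1G70830) was among the 5 largest falls, from 778 ± 89.8 to 1.55 ± 0.34. The list counts adjusted over the list alone were the same for these lists. In all 15534 genes were called, 2374 higher and 13160 lower. The median of all genes, -0.58, went to -0.04 with median-of-ratios scaling and the higher share from 15.3% to 47.0%. With it photosynthesis (-2.10), fatty acid synthesis (-1.03) and late embryogenesis kept their direction. The count was 9748 with a mean RPKM of at least 5.

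In dgat1-1 the same successive comparisons called 12224 genes between 8 and 12 DAF (5449 higher, 6775 lower) and 16031 between 12 and 16 DAF (1882 higher, 14149 lower). With a mean RPKM of at least 5 these counts were 7280 and 10027. With median-of-ratios scaling the higher share of the second went from 11.7% to 47.2%.

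At 8 DAF photosynthesis genes were lower in dgat1-1, and this list had the most called members, though not the largest share of its members called. Of 45 tested, 18 were lower and 0 higher, with a median log2 difference of -0.25, and 33 were lower and 1 higher when adjusted over the list alone. For photosynthesis camera gave a Benjamini-Hochberg adjusted p = 5.56e-31, and adjusted p = 0.125 with an estimated correlation. With other scalings 33 to 36 were lower. CAB3 (AT1G29910), a chlorophyll-binding protein, had 53.3 ± 1.60 RPKM in dgat1-1 and 122 ± 3.99 in WT (-1.18). CAB2 (AT1G29920) had 156 ± 2.62 and 238 ± 12.0 (-0.60). They are near-identical copies, so their separate values are uncertain. Genes of jasmonate synthesis and response were lower too, with 3 of 10 lower and 1 higher, and 6 lower and 1 higher adjusted over the list alone. For jasmonate camera gave a Benjamini-Hochberg adjusted p = 1.2e-06, and adjusted p = 0.0278 with an estimated correlation. The 3 lower genes were VSP2 (AT5G24770), 4.85 ± 0.21 against 13.7 ± 0.93 RPKM, VSP1 (AT5G24780), 0.77 ± 0.06 against 2.57 ± 0.50, and the lipoxygenase LOX2 (AT3G45140), 1.37 ± 0.14 against 3.26 ± 0.31.

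Some small heat shock proteins were near 0 in dgat1-1 at 8 DAF. HSP17.4 (AT3G46230) had 0.17 ± 0.23 RPKM against 8.45 ± 1.26 (-3.02) and HSP17.6C-CI (AT1G53540) 0.05 ± 0.04 against 1.29 ± 0.08 (-1.13). In all 4 of 13 were lower and 0 higher, or 5 lower adjusted over the list alone. For heat shock camera gave a Benjamini-Hochberg adjusted p = 2.52e-06, and adjusted p = 0.125 with an estimated correlation. Endosperm markers went the other way, with 4 of 8 higher and 1 lower (median 0.37), and 5 and 1 adjusted over the list alone. For endosperm camera gave a Benjamini-Hochberg adjusted p = 0.00214, and adjusted p = 0.0916 with an estimated correlation. FWA (AT4G25530) had 7.28 ± 0.17 against 4.57 ± 0.17 RPKM, FIS2 (AT2G35670) 4.58 ± 0.15 against 2.41 ± 0.30 and AGL40 (AT4G36590) 5.83 ± 0.81 against 2.93 ± 0.88. These 3 calls ended at a pseudocount of 0.1 (limma, Benjamini-Hochberg adjusted p = 0.179, 0.195 and 0.393, against at most 0.00105 as tested and down to 3.97e-08 over the alternatives). Of 11 genes of the unfolded protein response 1 was higher, SDF2 (AT2G25110) at 81.7 ± 0.66 against 66.6 ± 1.18 RPKM (0.29), and 8 adjusted over the list alone. For this response camera gave a Benjamini-Hochberg adjusted p = 0.000212, and adjusted p = 0.519 with an estimated correlation. With the other scalings 7 or 8 of them passed over all genes. Without WT library c the call of SDF2 ended (limma, Benjamini-Hochberg adjusted p = 0.0588, from 0.00038 to 0.0588 over the alternatives).

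Oil genes moved little at 8 DAF. Of 19 oil body genes 2 were lower and 0 higher, also adjusted over the list alone. They were OLEO2 (AT5G40420), an oleosin, at 18.4 ± 1.57 against 24.6 ± 1.28 RPKM (-0.40), and OLEO4 (AT3G27660) at 4.54 ± 1.03 against 5.98 ± 0.23. With other scalings 4 or 5 were lower. For oil bodies camera gave a Benjamini-Hochberg adjusted p = 0.00181, and adjusted p = 0.619 with an estimated correlation. The call of OLEO4 (limma, Benjamini-Hochberg adjusted p = 0.0328) ended under 5 alternatives and when any of 5 of its 6 libraries was left out (adjusted p from 0.000326 to 0.236 over the alternatives). DGAT3 (AT1G48300), a soluble acyltransferase, was higher at 37.0 ± 0.51 against 21.3 ± 0.95 RPKM (0.77; limma, Benjamini-Hochberg adjusted p = 1.68e-07). It was the 1 called gene of 25 in triacylglycerol assembly, and 1 was called adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.25). None of the other core genes was called, though FAD3 was higher with only the 2 groups in the model (limma, Benjamini-Hochberg adjusted p = 0.0274, up to 0.752 over the alternatives). The RPKM in dgat1-1 and WT was 15.01 and 13.8 for DGAT2 (AT3G51520), 4.25 and 3.66 for PDAT1 (AT5G13640) and 2.57 and 2.22 for PDAT2 (AT3G44830). It was 14.4 and 14.9 for LPCAT2 (AT1G63050), 8.72 and 8.17 for ROD1 (AT3G15820) and 355 and 345 for FAD2 (AT3G12120). Mean RPKM was 35.7 and 32.8 for FAD3 (AT2G29980) and 4.38 and 4.14 for FAE1 (AT4G34520). Among regulators it was 75.6 and 74.0 for the fatty acid regulator WRI1 (AT3G54320), 82.6 and 82.2 for LEC1 (AT1G21970), 19.8 and 19.9 for FUS3 (AT3G26790), and 8.22 and 8.62 for ABI3 (AT3G24650). Mean RPKM was 22.5 and 26.3 for OLEO1 (AT4G25140), 5.04 and 5.55 for CRA1 and 4.75 and 4.29 for the lipase SDP1 (AT5G04040).

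Among further genes at 8 DAF, DIN10 (AT5G20250, 24.96 ± 1.35 against 16.5 ± 0.31 RPKM) and the starch phosphorylase PHS1 (AT3G29320, 75.1 ± 2.94 against 56.7 ± 1.1) were higher. The cutin gene BDG1 (AT1G64670, 21.9 ± 0.07 against 14.7 ± 0.11) and the fruit gene SHP1 (AT3G58780, 51.1 ± 1.97 against 34.7 ± 0.96) were higher too. The wax gene CER3 (AT5G57800, 10.9 ± 0.23 against 17.2 ± 0.24) and the seed coat genes TT10 (AT5G48100, 220 ± 6.95 against 286 ± 1.06) and MUM4 (AT1G53500, 119 ± 3.46 against 160 ± 0.78) were lower. So were AFR (AT2G24540, 0.09 ± 0.12 against 7.34 ± 2.55) and AT2G45220 (6.52 ± 0.06 against 19.6 ± 0.23). Among the 8 largest rises were AT3G30836, a transposable element gene, at 17.2 ± 0.46 against 0.01 RPKM (4.17), AT1G78780 at 19.4 ± 0.95 against 2.09 ± 0.39 (2.72) and AT1G62220 at 10.3 ± 0.24 against 1.25 ± 0.35 (2.33). AT4G19240 was listed at 0 in the 3 WT libraries and at 8.94, 8.04 and 8.95 RPKM in those of dgat1-1. Camera also passed plastid fatty acid synthesis, late embryogenesis, sucrose use, abscisic acid and mucilage as lower and galactolipids as higher, with at most 1 member of each called, or 2 adjusted over the list alone. Their Benjamini-Hochberg adjusted p ran from 0.0192 to 0.0473, and adjusted p from 0.545 to 0.862 with an estimated correlation. With other scalings 8 to 10 of 37 fatty acid synthesis genes, 3 of 16 abscisic acid genes and 2 to 4 of 17 mucilage genes were lower. The call of late embryogenesis, whose median of 0.01 differs in sign from its test, ended with median-of-ratios (adjusted p = 0.306) and rDNA scaling (adjusted p = 0.229, from 0.0378 to 0.619 over the alternatives). The other lists did not pass. Storage proteins, seed maturation regulators, oil breakdown and cell division had 0 called members. Starch synthesis had 1 higher and 1 lower, starch breakdown 1 higher, low-sugar response 2 higher, seed coat flavonoids 2 higher and 1 lower, suberin, cutin and wax 3 higher and 1 lower, and silique wall 1 higher. With median-of-ratios scaling low-sugar response had 4 higher and 1 lower, flavonoids 2 and 4, suberin, cutin and wax 6 and 2, regulators 1 and 2 and oil breakdown 0 and 1.

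In total 752 of 18906 genes were called at 8 DAF, 456 higher (60.6%) and 296 lower. Of these, 91 differed by at least 1 (75 higher, 16 lower). The count was 480 with a mean RPKM of at least 5 and 499 with a pseudocount of 0.1. It was 497 without dgat1-1 library a and 499 without WT library b, 1195 to 1339 with other scalings and 2739 with only the 2 groups in the model. The higher share was 48.7% with a pseudocount of 0.1 and 40.1% with median-of-ratios scaling, so which direction was more frequent depended on the setting.

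At 12 DAF storage protein transcripts were lower in dgat1-1 while those of fatty acid synthesis were higher. Of 13 storage protein genes 7 were lower and 0 higher, and 9 lower adjusted over the list alone, with a median log2 difference of -0.50. For storage proteins camera gave a Benjamini-Hochberg adjusted p = 5.46e-11, and adjusted p = 0.261 with an estimated correlation. SESA1 (AT4G27140) had 724 ± 22.4 RPKM against 2783 ± 178 in WT (-1.94) and SESA5 (AT5G54740) 281 ± 11.3 against 654 ± 46.8 (-1.22). CRU3 (AT4G28520) had 3222 ± 244 against 8267 ± 703 (-1.36) and CRA1 2186 ± 93.6 against 5249 ± 385 (-1.26). Of 37 genes of plastid fatty acid synthesis 24 were higher and 0 lower, with a median of 0.29, and 29 higher and 1 lower adjusted over the list alone. For fatty acid synthesis camera gave a Benjamini-Hochberg adjusted p = 1.2e-05, and adjusted p = 0.647 with an estimated correlation. The acyl carrier protein ACP5 (AT5G27200) had 375 ± 21.2 against 265 ± 19.02 RPKM (0.50). BADC2 (AT1G52670), known to restrain acetyl-CoA carboxylase, had 242 ± 12.0 against 176 ± 13.1 (0.46) and MCAMT (AT2G30200) 121 ± 9.05 against 89.3 ± 9.45 (0.44).

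Suberin, cutin and wax genes were lower at 12 DAF, with 10 of 21 lower and 3 higher, also adjusted over the list alone (median -0.21). For suberin, cutin and wax camera gave a Benjamini-Hochberg adjusted p = 5.67e-07, and adjusted p = 0.468 with an estimated correlation. FAR1 (AT5G22500) had 1.90 ± 0.14 against 7.57 ± 1.53 RPKM (-1.55). GPAT5 (AT3G11430) had 0.38 ± 0.06 against 2.50 ± 0.46 (-1.33) and LACS2 (AT1G49430) 9.17 ± 0.56 against 16.7 ± 1.71 (-0.79). Photosynthesis genes were again lower, 20 of 45 with 0 higher, and 22 lower adjusted over the list alone (median -0.19). For photosynthesis camera gave a Benjamini-Hochberg adjusted p = 3.18e-13, and adjusted p = 0.468 with an estimated correlation. Without the top 100 genes 31 were lower. CAB2 was at 198 ± 12.7 against 398 ± 35.1 RPKM (-1.01) and CAB3 at 354 ± 18.6 against 599 ± 48.5 (-0.76). Starch breakdown was higher, 8 of 11 with 0 lower, also adjusted over the list alone (median 0.39). For starch breakdown camera gave a Benjamini-Hochberg adjusted p = 0.000285, and adjusted p = 0.519 with an estimated correlation. The isoamylase ISA3 (AT4G09020) was at 39.9 ± 2.58 against 22.6 ± 1.99 RPKM (0.80), PHS2 (AT3G46970) at 34.4 ± 2.04 against 24.1 ± 2.80 (0.50) and PHS1 at 50.4 ± 4.19 against 37.0 ± 2.80 (0.43). Cell division genes were higher, 11 of 26 with 0 lower, and 15 adjusted over the list alone (median 0.26). For cell division camera gave a Benjamini-Hochberg adjusted p = 0.000293, and adjusted p = 0.519 with an estimated correlation. With median-of-ratios scaling 5 were higher. Those called over all genes included the cyclin CYCB1;1 (AT4G37490) at 6.99 ± 1.08 against 4.18 ± 0.50 RPKM (0.62). PCNA1 (AT1G07370) was at 12.4 ± 0.36 against 8.78 ± 0.52 (0.45) and the kinesin HINKEL (AT1G18370) at 11.9 ± 1.49 against 8.32 ± 0.12 (0.46). The call of PCNA1 ended at a pseudocount of 0.1 (limma, Benjamini-Hochberg adjusted p = 0.141, from 3.9e-05 to 0.141 over the alternatives).

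Heat shock proteins were lower at 12 DAF, 4 of 13 with 1 higher, also adjusted over the list alone. For heat shock camera gave a Benjamini-Hochberg adjusted p = 0.00189, and adjusted p = 0.428 with an estimated correlation. Among the lower were HSP17.6A-CI (AT1G59860) at 4.41 ± 0.85 against 8.87 ± 0.50 RPKM (-0.88) and HSP101 (AT1G74310) at 10.04 ± 1.23 against 15.4 ± 2.03 (-0.57). Jasmonate genes went both ways, 3 higher and 3 lower of 10, and 3 and 5 adjusted over the list alone. For jasmonate camera pointed down (Benjamini-Hochberg adjusted p = 0.0192, and adjusted p = 0.322 with an estimated correlation), a call that ended with median-of-ratios scaling (adjusted p = 0.125, from 0.0189 to 0.322 over the alternatives). With that scaling 1 was higher and 4 lower. AOC3 (AT3G25780) had 11.2 ± 0.95 against 18.5 ± 1.90 RPKM (-0.67). With only the 2 groups in the model the calls of MCAMT, CYCB1;1, HINKEL and HSP101 at 12 DAF ended (limma, Benjamini-Hochberg adjusted p = 0.0547, 0.0538, 0.0618 and 0.0547, in each case the highest over the alternatives).

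Oil assembly genes split at 12 DAF. In triacylglycerol assembly 5 of 25 were higher and 2 lower, or 7 and 2 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.639). The acyltransferases PDAT2 (11.6 ± 0.38 against 7.14 ± 0.63 RPKM, 0.63) and LPCAT2 (28.1 ± 2.84 against 20.3 ± 2.80, 0.45) and the desaturase FAD3 (317 ± 22.01 against 272 ± 19.8, 0.22) were higher. DGAT3 was lower (51.8 ± 1.56 against 63.1 ± 6.57, -0.28). Of oil body genes 3 of 19 were higher and 3 lower, or 7 and 4 adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.674). The sterol dehydrogenase HSD1 (AT5G50600) was at 101 ± 2.89 against 310 ± 41.9 RPKM (-1.60) and OLEO3 (AT5G51210) at 1747 ± 35.3 against 1189 ± 55.2 (0.56). LEC1 was higher (22.2 ± 1.46 against 18.24 ± 2.41, 0.28). With only the 2 groups in the model the calls of DGAT3, LPCAT2, FAD3 and LEC1 ended (limma, Benjamini-Hochberg adjusted p = 0.139, 0.0848, 0.21 and 0.215, in each case the highest over the alternatives). Those of FAD3 and LEC1 also ended without the top 100 genes and without WT library b or dgat1-1 library a or b. DGAT2 (22.2 ± 1.69 against 21.04 ± 1.92), PDAT1 (2.41 ± 0.07 against 2.40 ± 0.10), FAD2 (581 ± 62.1 against 534 ± 62.5) and FAE1 (260 ± 37.2 against 236 ± 38.4) were not called. Nor were ABI3 (58.1 ± 5.05 against 55.7 ± 3.69), OLEO1 (7724 ± 439 against 6860 ± 591) and SDP1 (5.71 ± 0.45 against 5.85 ± 0.89), though OLEO1 was higher with voom (adjusted p = 0.0435, up to 0.79 over the alternatives). ROD1 (74.2 ± 5.54 against 64.3 ± 6.39) and FUS3 (84.8 ± 5.97 against 73.6 ± 6.94) were not called either but were higher under 4 and 5 alternatives. WRI1 (110 ± 11.0 against 120 ± 14.7) was lower with each of the 4 other scalings.

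Further genes at 12 DAF were among the largest differences. GRP7 (AT2G21660), a clock-regulated RNA-binding protein, had 520 ± 60.2 RPKM against 97.9 ± 15 (2.40). CYP81D6 (AT2G23220) had 12.0 ± 2.58 against 0.57 ± 0.29 (3.05) and AT2G33830 28.8 ± 3.64 against 3.79 ± 0.23 (2.63). AT3G30836 (10.9 ± 1.43 RPKM against a WT mean rounded to 0) stayed higher, and so did AT4G19240 (9.35, 8.44 and 6.63 in dgat1-1, at 0, 0.04 and 0 in WT). AT5G44550 (0.97 ± 0.22 against 18.9 ± 2.44, -3.34), AT3G04190 (1.45 ± 0.38 against 22.2 ± 2.53, -3.25) and the cold-responsive KIN2 (AT5G15970, 0.67 ± 0.29 against 11.0 ± 1.86, -2.84) were lower. The lipid transfer protein gene DIR1 (AT5G48485) was listed at 21.9, 24.7 and 23.3 RPKM in the WT libraries of 12 DAF and at 0 in the other 15 libraries, which can mean a failed estimate, so no fold is given. The trichome and seed coat regulator GL2 (AT1G79840, 27.8 ± 0.85 against 47.8 ± 2.71, -0.76) and MUM4 (81.0 ± 5.12 against 120 ± 14.1, -0.56) were lower. BXL1 (AT5G49360, 152 ± 3.39 against 88.9 ± 5.98, 0.77) and the glucose phosphate carrier GPT2 (AT1G61800, 87.7 ± 7.87 against 50.3 ± 6.02, 0.79) were higher. Lists that did not pass, as higher and lower members, were late embryogenesis (7 and 6), seed maturation regulators (3 and 3), oil breakdown (2 and 3), starch synthesis (5 and 2), sucrose use (5 and 0) and low-sugar response (0 and 0). Further such lists were abscisic acid (2 and 1), unfolded protein response (3 and 0), galactolipids (1 and 0), seed coat flavonoids (7 and 3), mucilage (4 and 5), endosperm (0 and 1) and silique wall (1 and 1). With median-of-ratios scaling more of them leaned lower: regulators had 2 higher and 8 lower, mucilage 2 and 9, late embryogenesis 5 and 8, oil breakdown 1 and 4 and low-sugar response 0 and 3. Sucrose use then had 3 and 2, abscisic acid 2 and 3, the unfolded protein response 3 and 2, starch synthesis 4 and 3 and flavonoids 6 and 5. In 7 of the lists that did not pass, such as oil bodies and late embryogenesis, camera pointed down although the median or the mean lay above 0. Mucilage passed as lower with median-of-ratios scaling (camera, Benjamini-Hochberg adjusted p = 0.0255) and rDNA rescaling (adjusted p = 0.0265). With rDNA rescaling the unfolded protein response passed as higher (camera, Benjamini-Hochberg adjusted p = 0.0418).

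In total 4246 genes were called at 12 DAF, 3352 higher (78.9%) and 894 lower, and of the 196 that differed by at least 1, 92 were higher and 104 lower. The higher share was 49.3% with median-of-ratios scaling, and the count was 854 with only the 2 groups in the model. Replicates differed more at 12 DAF (SD of the log2 difference 0.224 to 0.294) than at 8 DAF (0.150 to 0.163). The spread shared by the 6 groups is thus small for 12 DAF. Without WT library b, in which 33.6% of reads fell on rDNA against 22.6% and 25.3% in the other 2, the count was 3425 (2121 higher, 1304 lower).

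At 16 DAF the genotypes differed most, and all 23 genes of the late embryogenesis list were lower in dgat1-1, with a median log2 difference of -2.10, and 23 were lower adjusted over the list alone. For late embryogenesis camera gave a Benjamini-Hochberg adjusted p = 1.94e-31, and adjusted p = 0.00108 with an estimated correlation. EM1 had 5.12 ± 0.32 RPKM against 188 ± 15.1 in WT (-4.95) and EM6 (AT2G40170) 1.12 ± 0.37 against 49.3 ± 1.59 (-4.58). The dehydrin RAB18 (AT5G66400) had 41.3 ± 2.85 against 553 ± 37.7 (-3.71), M10 (AT2G41280) 0.08 ± 0.14 against 12.4 ± 0.53 (-3.64) and AT2G42560 3.99 ± 0.17 against 49.3 ± 4.52 (-3.33). ECP31 (AT3G22500) was listed at 10.6, 9.48 and 9.69 RPKM in WT and at 0 in all 3 libraries of dgat1-1. Outside the list AT1G54870 (16.9 ± 0.87 against 493 ± 32.6, -4.79), AT3G05260 (3.31 ± 0.48 against 64.4 ± 1.72, -3.93) and AT4G11310, a cysteine proteinase (6.30 ± 0.38 against 78.8 ± 3.32, -3.45), were lower by similar sizes. Heat shock proteins were lower too, 9 of 13 with 1 higher, also adjusted over the list alone (median -0.51). For heat shock camera gave a Benjamini-Hochberg adjusted p = 6.46e-06, and adjusted p = 0.127 with an estimated correlation. HSP17.6A (AT5G12030) was at 0.01 ± 0.02 against 8.93 ± 0.38 RPKM, HSP70B (AT1G16030) at 2.60 ± 0.11 against 14.8 ± 0.61 and the seed heat shock factor HSFA9 (AT5G54070) at 0.08 ± 0.08 against 4.01 ± 0.29.

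**Figure D3:**
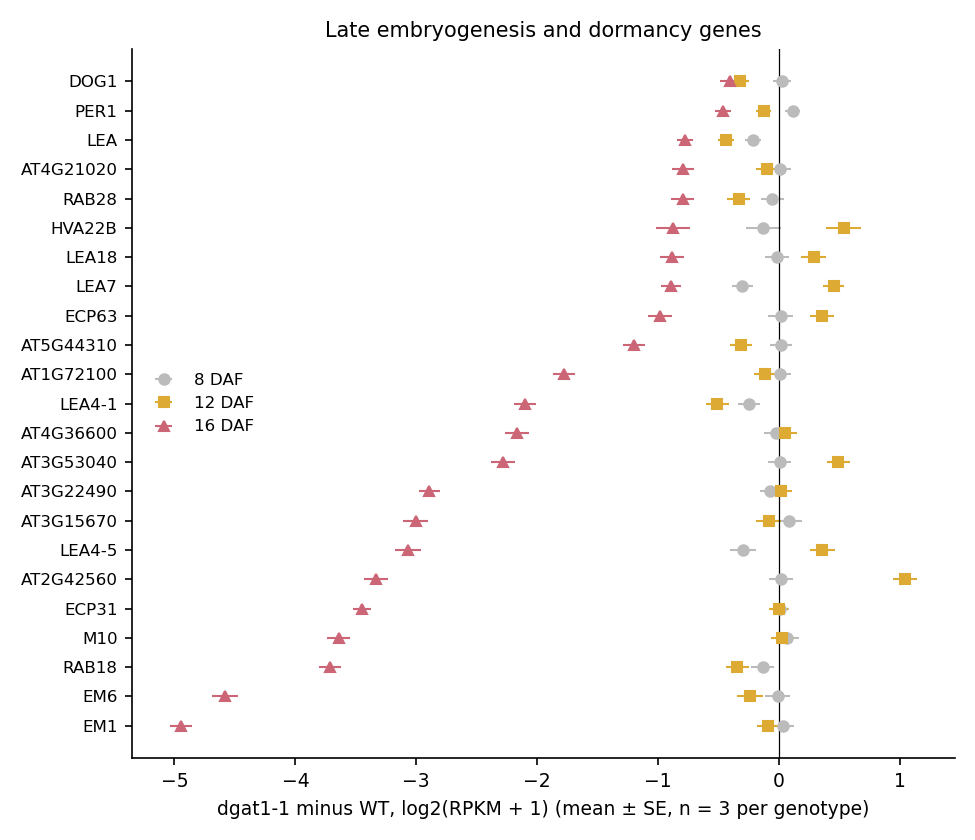
Difference of dgat1-1 minus WT in log2(RPKM + 1) (horizontal axis, mean ± SE, 3 libraries per genotype) for each of the 23 late embryogenesis and dormancy genes at 8, 12 and 16 DAF. All 23 lie below 0 at 16 DAF, where the median is -2.10.

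Plastid fatty acid synthesis was higher in dgat1-1 at 16 DAF, with 33 of 37 genes higher and 0 lower, also adjusted over the list alone (median 0.56). For fatty acid synthesis camera gave a Benjamini-Hochberg adjusted p = 7.74e-12, and adjusted p = 0.538 with an estimated correlation. ACP5 had 91.3 ± 2.23 RPKM against 36.7 ± 1.68 (1.29) and the stearoyl desaturase FAB2 (AT2G43710) 437 ± 15.9 against 205 ± 13.4 (1.09). The regulators WRI1 (59.7 ± 1.46 against 25.6 ± 1.02, 1.19) and L1L (AT5G47670, 33.3 ± 0.49 against 12.7 ± 1.65, 1.33) were higher. In triacylglycerol assembly 11 of 25 were higher and 6 lower, also adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.426). DGAT2 (15.8 ± 0.69 against 10.6 ± 0.08, 0.54), PDAT2 (11.9 ± 0.58 against 7.74 ± 0.28, 0.56), LPCAT2 (12.5 ± 1.17 against 8.27 ± 0.70, 0.54) and ROD1 (49.9 ± 1.90 against 26.1 ± 1.52, 0.91) were higher. So were FAD2 (790 ± 54.2 against 525 ± 49.0, 0.59), FAD3 (960 ± 29.7 against 661 ± 34.6, 0.54), the elongase FAE1 (281 ± 10.3 against 173 ± 12.3, 0.70) and ABI3 (73.5 ± 1.41 against 60.3 ± 3.23, 0.28). SDP1 was lower (4.21 ± 0.17 against 6.84 ± 0.66, -0.59). LEC1 was lower as well (0.89 ± 0.09 against 1.21 ± 0.12, -0.22; limma, Benjamini-Hochberg adjusted p = 0.0366), a call that ended under 4 alternatives and without 4 of the 6 libraries (adjusted p from 4.69e-05 to 0.409 over the alternatives). DGAT3 (124 ± 2.18 against 113 ± 4.03), PDAT1 (1.16 ± 0.41 against 1.37 ± 0.17), FUS3 (51.7 ± 1.24 against 48.5 ± 2.44) and OLEO1 (19641 ± 779 against 17287 ± 1167) were not called. DGAT3, FUS3 and OLEO1 were higher with rescaling to reads outside the rDNA loci (limma, Benjamini-Hochberg adjusted p = 1.03e-05, 6.68e-05 and 0.00124). Over the alternatives these adjusted p ran up to 0.418, 0.917 and 0.395, and that of OLEO1 down to 0.000168. PDAT1 was lower without dgat1-1 library b (adjusted p = 0.0346, up to 0.931 over the alternatives).

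Photosynthesis, lower at the earlier stages, was higher in dgat1-1 at 16 DAF, with 31 of 45 genes higher and 3 lower (median 0.48), and 32 and 4 adjusted over the list alone. For photosynthesis camera gave a Benjamini-Hochberg adjusted p = 3.33e-07, and adjusted p = 0.619 with an estimated correlation. PSAO (AT1G08380) had 58.9 ± 1.64 RPKM against 21.6 ± 1.62 (1.41), PSBQ2 (AT4G05180) 106 ± 3.43 against 50.6 ± 2.40 (1.05) and LHCB6 (AT1G15820) 56.3 ± 2.44 against 32.2 ± 0.92 (0.79). Starch synthesis was higher, 11 of 15 with 2 lower, or 11 and 3 adjusted over the list alone (median 0.46). For starch synthesis camera gave a Benjamini-Hochberg adjusted p = 0.0035, and adjusted p = 0.647 with an estimated correlation. Starch breakdown was higher as well, 7 of 11 with 1 lower, also adjusted over the list alone (median 0.86). For starch breakdown camera gave a Benjamini-Hochberg adjusted p = 0.000293, and adjusted p = 0.519 with an estimated correlation. GPT2 had 129 ± 3.40 against 30.1 ± 1.61 RPKM (2.06) and PHS1 30.0 ± 1.20 against 7.34 ± 0.95 (1.90). PHS2 had 18.98 ± 0.25 against 5.87 ± 0.66 (1.54), ISA3 16.2 ± 0.88 against 5.91 ± 0.40 (1.32) and the starch synthase GBSS1 (AT1G32900) 7.65 ± 1.05 against 3.72 ± 0.17 (0.87). Of the sucrose synthases, SUS2 (AT5G49190) was higher (241 ± 9.67 against 139 ± 9.24) and SUS3 (AT4G02280) lower (11.6 ± 0.51 against 35.6 ± 2.25). Of 26 cell division genes 8 were higher, 0 lower and 18 not called, also adjusted over the list alone. Of all 18906 genes tested 4756 were higher. Among the 8 was KNOLLE (AT1G08560) at 3.36 ± 1.06 against 0.67 ± 0.21 RPKM. For cell division camera gave a Benjamini-Hochberg adjusted p = 0.0147, and adjusted p = 0.647 with an estimated correlation. Camera no longer passed it with rescaling to reads outside the rDNA loci (adjusted p = 0.109, from 0.00152 to 0.647 over the alternatives), although 14 were then higher. With median-of-ratios scaling 12 were higher.

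Storage and oil body transcripts split at 16 DAF. Of 13 storage protein genes 5 were lower and 2 higher, also adjusted over the list alone (median -0.18). For storage proteins camera gave a Benjamini-Hochberg adjusted p = 0.0426, and adjusted p = 0.701 with an estimated correlation. It no longer passed with median-of-ratios scaling (adjusted p = 0.0993, from 0.0397 to 0.701 over the alternatives), and with rescaling to reads outside the rDNA loci 3 were higher and 4 lower. SESA1 (3245 ± 99.8 against 8519 ± 400, -1.39), CRU3 (18209 ± 765 against 43302 ± 2586, -1.25) and CRA1 (9977 ± 422 against 17532 ± 776, -0.81) were lower. The cupin AT4G36700 was higher (1299 ± 92.0 against 789 ± 41.0, 0.72). Of 19 oil body genes 9 were lower and 3 higher, also adjusted over the list alone (median -0.24). For oil bodies camera gave a Benjamini-Hochberg adjusted p = 0.0147, and adjusted p = 0.647 with an estimated correlation. HSD1 was at 208 ± 11.6 against 837 ± 23.3 RPKM (-2.004), SEIPIN1 (AT5G16460) at 3.51 ± 0.10 against 10.6 ± 0.76 (-1.36) and OLEO3 at 1217 ± 61.0 against 538 ± 28.01 (1.18). With rescaling to reads outside the rDNA loci 6 were higher and 7 lower. Of 21 oil breakdown genes 10 were lower and 5 higher, or 11 and 7 adjusted over the list alone, with malate synthase MLS (AT5G03860) at 7.38 ± 0.42 against 22.5 ± 1.53 RPKM (-1.49). For oil breakdown camera gave a Benjamini-Hochberg adjusted p = 0.0364, and adjusted p = 0.701 with an estimated correlation. That call ended with rescaling to reads outside the rDNA loci (adjusted p = 0.0988, from 0.0226 to 0.701 over the alternatives), where 8 were higher and 8 lower (median -0.008).

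Hormone and surface lists were lower at 16 DAF. Of 16 abscisic acid genes 9 were lower and 2 higher, or 10 and 2 adjusted over the list alone (median -0.48). For abscisic acid camera gave a Benjamini-Hochberg adjusted p = 0.00167, and adjusted p = 0.619 with an estimated correlation. Among the lower were phosphatases known to act against abscisic acid signalling, HAI1 (AT5G59220, 29.8 ± 0.39 against 55.2 ± 4.50 RPKM), HAI2 (AT1G07430, 2.38 ± 0.20 against 6.15 ± 0.21) and HAI3 (AT2G29380, 0.13 ± 0.15 against 1.43 ± 0.23). Of 10 jasmonate genes 7 were lower and 0 higher, or 8 adjusted over the list alone (median -0.46). For jasmonate camera gave a Benjamini-Hochberg adjusted p = 0.000285, and adjusted p = 0.0916 with an estimated correlation. LOX2 was at 3.45 ± 0.26 against 7.82 ± 0.87 and AOC3 at 2.16 ± 0.24 against 4.39 ± 0.51. Of 21 suberin, cutin and wax genes 13 were lower and 3 higher, or 15 and 3 adjusted over the list alone (median -0.38). For suberin, cutin and wax camera gave a Benjamini-Hochberg adjusted p = 0.000525, and adjusted p = 0.619 with an estimated correlation. FAR5 (AT3G44550) was lower (9.29 ± 0.23 against 17.41 ± 0.46, -0.84), a call that ended at a pseudocount of 0.1 (limma, Benjamini-Hochberg adjusted p = 0.0508, from 3.8e-11 to 0.0508 over the alternatives). BDG1 (5.78 ± 0.30 against 2.69 ± 0.36, 0.88) and DCR (AT5G23940, 59.4 ± 1.61 against 33.2 ± 0.90, 0.82) were higher. Lists that did not pass, as higher and lower members, were seed maturation regulators (6 and 8, or 11 and 4 with rescaling to reads outside the rDNA loci), sucrose use (5 and 3), low-sugar response (3 and 6) and unfolded protein response (6 and 2, with PDIL1-1, AT1G21750, at 225 ± 5.03 against 122 ± 5.32 RPKM). Further such lists were galactolipids (1 and 3), seed coat flavonoids (5 and 4), mucilage (5 and 4), endosperm (0 and 0) and silique wall (1 and 2). With rescaling to reads outside the rDNA loci flavonoids had 8 and 4 and mucilage 8 and 3. For regulators, sucrose use and flavonoids camera pointed down although the median or the mean lay above 0. Low-sugar response passed as lower with rDNA rescaling (camera, Benjamini-Hochberg adjusted p = 0.0408).

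**Figure D4:**
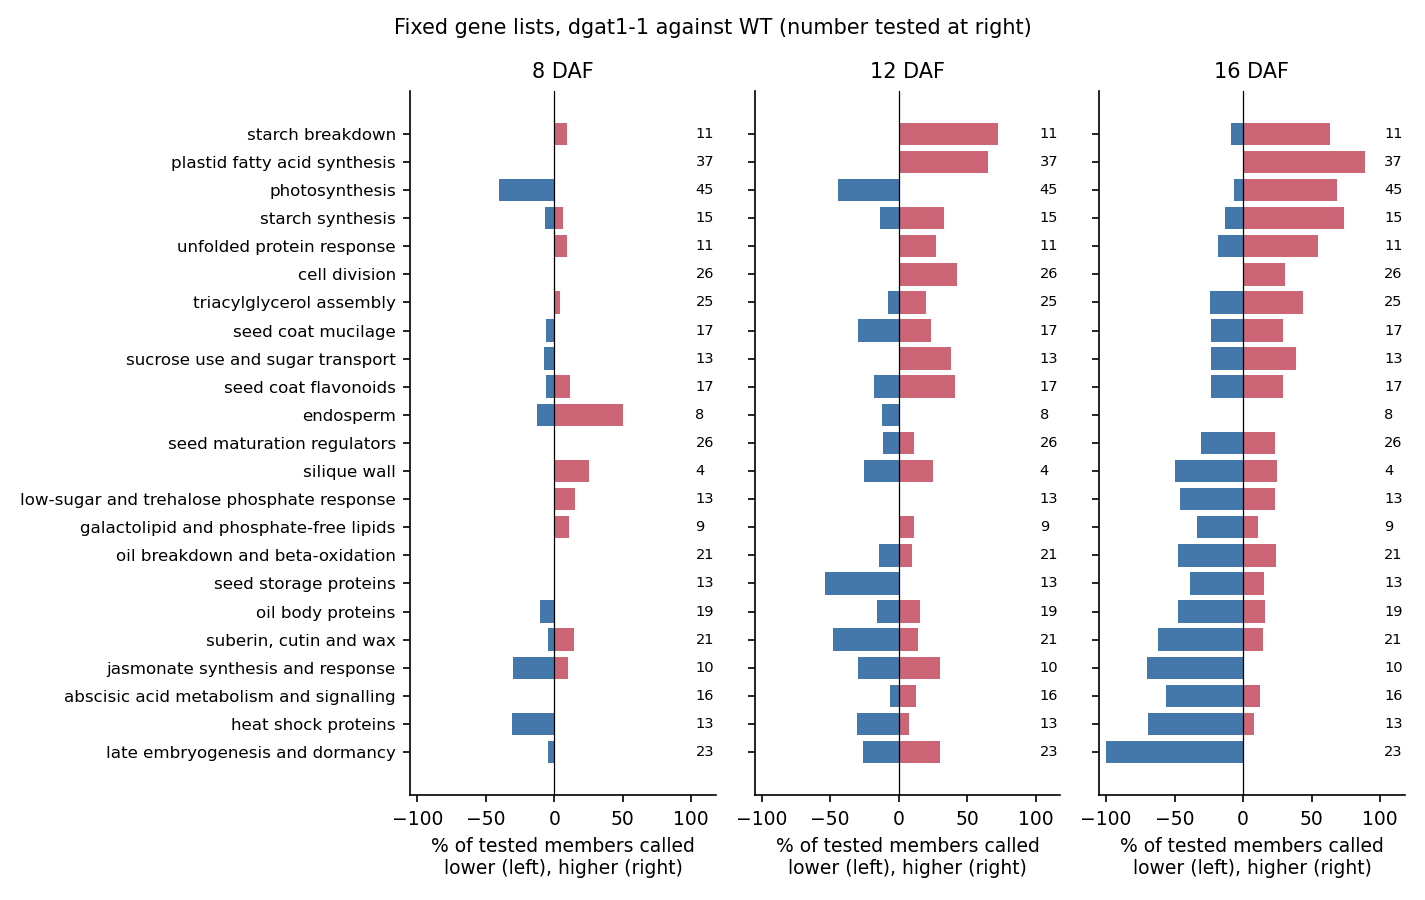
Share of each list's tested members called lower (left) or higher (right) in dgat1-1 at 8, 12 and 16 DAF (horizontal axis, percent; number tested at the right of each bar). Photosynthesis had 18 and 20 of 45 members lower at 8 and 12 DAF and 31 higher at 16 DAF, and late embryogenesis had all 23 lower at 16 DAF.

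The largest rises at 16 DAF were AT1G21520 (25.8 ± 0.41 against 0.38 ± 0.10 RPKM, 4.28), AT1G47395, an iron-regulated peptide gene (16.2 ± 2.44 against 0.14 ± 0.02, 3.90) and AT3G02790 (35.6 ± 3.12 against 1.79 ± 0.79, 3.75). AT3G30836 (9.72 ± 0.44 against 0.01 ± 0.01, 3.41) and CYP81D6 (10.2 ± 0.20 against 0.07 ± 0.03, 3.40) followed. RALFL32 (AT4G14010) was listed at 5.62, 8.93 and 7.31 RPKM in dgat1-1 at 16 DAF and at 0 in the other 15 libraries. DIR1 was the only other gene listed at 0 in every library of 5 groups and at 5 or more in every library of the sixth. In total 7753 genes were called, 4756 higher (61.3%) and 2997 lower. Of them 614 differed by at least 1 (345 higher, 269 lower). The higher share was 50.5% with median-of-ratios scaling and 79.9% with rescaling to reads outside the rDNA loci, which took the median of all genes from 0.04 to 0.15. Groups did not overlap for 6607 genes (34.9%) at 8 DAF, 4876 (25.8%) at 12 DAF and 9571 (50.6%) at 16 DAF, where chance gives 10% without a shift of whole libraries. These counts used unscaled RPKM, which moves with the rDNA share. That share did not overlap at 8 DAF (37.3% to 37.9% in WT, 34.1% to 35.6% in dgat1-1). Nor did it at 16 DAF (19.9% to 26.2% in WT, 30.2% to 32.8% in dgat1-1), so part of these counts can come from it.

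Averaged over the stages, 7104 genes were called in dgat1-1 against WT, 5250 higher (73.9%) and 1854 lower, and the higher share was 49.6% with median-of-ratios scaling. Genes called at both 12 and 16 DAF mostly moved the same way. Of them 1678 were higher at both, where 843 were expected from independent lists, and 439 were lower at both, where 142 were expected. Between 8 and 12 DAF, 156 genes were higher at both against 80.8 expected and 107 were lower at both against 14 expected. Between 8 and 16 DAF, 124 genes were higher at both against 115 expected (Fisher's exact test, p = 0.168) and 93 were lower at both against 46.9 expected. Of the 369 genes called at both 8 and 16 DAF, 217 moved the same way and 152 opposite ways. At all 3 stages 213 genes were called, of which 80 were higher and 50 lower throughout.

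The genotype effect differed between stages for 6062 of 18906 genes by the interaction test. Between 12 and 8 DAF it differed for 1331 genes, between 16 and 12 DAF for 4602 and between 16 and 8 DAF for 5300. Among genes with a mean RPKM of at least 5, the 6 with the smallest interaction p were AT1G54870, EM1, AT3G05260, EM6, AT4G11310 and AT2G42560, and all had their large fall at 16 DAF (limma, Benjamini-Hochberg adjusted p from 2.24e-16 to 2.14e-14). AT2G42560 was higher in dgat1-1 at 12 DAF (4.31 against 1.58 RPKM, 1.05). SESA1 (adjusted p = 8.54e-12 by limma with Benjamini-Hochberg), WRI1 (4.32e-08) and DGAT3 (2.05e-07) differed between stages too. Of the core genes DGAT1 (0.0817), PDAT1 (0.266) and FUS3 (0.256) had an interaction that was not called.

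Position on the WT developmental axis was measured as the slope, across 18906 genes, of the genotype effect on the WT change between the other 2 stages. Only at 12 DAF, where that change runs from 8 to 16 DAF, does a slope below 0 lie on the younger side. The slope at 12 DAF was -0.0425 ± 0.0003 (SD over 3 dgat1-1 libraries), with all 3 between -0.0428 and -0.0423. That SD leaves out the spread of WT, since each library was set against the same WT mean. Pooled over the libraries of both genotypes, the SD at 12 DAF was 0.0013. Single WT libraries against the other 2 gave slopes between -0.002 and 0.003 (exact permutation p = 0.1, two-sided, the smallest that 10 splits allow). The correlation across genes, which are not independent replicates, was r = -0.237. At 8 DAF the slope was 0.0105 ± 0.0039 and at 16 DAF 0.012 ± 0.0042 (exact permutation p = 0.1 for each, the smallest possible). The pooled SD was 0.003 at 8 DAF and 0.0056 at 16 DAF. Single WT libraries against the other 2 gave slopes between -0.0025 and 0.0019 at 8 DAF. At 16 DAF they gave slopes between -0.0116 and 0.0063, the lowest about as far from 0 as the genotype slope there. With a mean RPKM of at least 5 the slope at 16 DAF was -0.0011, of the opposite sign. The axis at 16 DAF was the WT change from 8 to 12 DAF, which does not include the 12 to 16 DAF step. That at 8 DAF was the WT change from 12 to 16 DAF, which does not include the 8 to 12 DAF step. The 2 steps can run in opposite directions, as for photosynthesis genes in WT (medians of 1.005 from 8 to 12 DAF and -2.821 from 12 to 16 DAF). The sign of the slope at 8 DAF therefore does not say younger or older.

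By the p-values of the authors' deposited table, 348 features were under 0.05 at 8 DAF, 199 higher and 149 lower in dgat1-1. The authors' deposited table gave 763 at 12 DAF (378 higher, 385 lower) and 1560 at 16 DAF (790 higher, 770 lower). The authors' deposited table and the limma test thus both gave the most differences at 16 DAF. Both gave the fewest at 8 DAF when limma used all 6 groups, but with only the 2 groups in the model limma gave 2739 at 8 DAF and 854 at 12 DAF. By groups that did not overlap, too, fewer genes differed at 12 DAF than at 8 DAF. That count used unscaled RPKM, and at 8 DAF the rDNA share itself did not overlap between the genotypes. The counts come from different tests and sets of features.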

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

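The tests of explanations and the counts over other splits in this part were chosen after the results were seen, while the interaction tests were fixed beforehand. What called for a closer look was a genotype effect that differed between stages. That was the case for 6062 genes by the interaction test, for 1331 between 12 and 8 DAF, 4602 between 16 and 12 DAF and 5300 between 16 and 8 DAF. Of the 112 genes named in the report ahead of this part, 106 had an interaction that was called, against 32.1% of all genes tested. The naming rule took genes with large differences or small p in these same data, so that share is no test. Genes named only from here on are not counted among the 112.

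The interaction p of these 106 genes follows, from limma with Benjamini-Hochberg adjustment. Among late embryogenesis genes it was 2.24e-16 for EM1, 4.92e-15 for ECP31, 1.25e-14 for EM6, 2.14e-14 for AT2G42560, 3.31e-14 for M10 and 5.13e-14 for RAB18. Among heat shock genes the value was 1.15e-12 for HSP17.6A, 9.1e-12 for HSFA9, 1.16e-10 for HSP70B, 3.8e-07 for HSP17.4, 9.75e-06 for HSP17.6C-CI, 0.000294 for HSP17.6A-CI and 0.000396 for HSP101. Among storage protein genes it stood at 8.54e-12 for SESA1, 1.45e-05 for CRU3, 1e-04 for SESA5, 0.000336 for AT4G36700, 0.00052 for CRA1 and 0.0285 for SESA2. Among oil body genes it came to 7.09e-11 for HSD1, 1.73e-09 for OLEO3, 1.37e-06 for SEIPIN1, 0.00068 for OLEO2, 0.00604 for OLEO4 and 0.0491 for OLEO1. Among photosynthesis genes it was 3.48e-10 for CAB3, 2.38e-09 for PSBQ2, 2.41e-09 for PSAO, 1.75e-07 for LHCB6 and 2.7e-05 for CAB2. Among starch breakdown genes the value was 2.83e-09 for PHS1, 4.67e-08 for PHS2 and 3.38e-07 for ISA3. Among seed maturation regulator genes it stood at 1.73e-08 for L1L, 4.32e-08 for WRI1, 1.7e-06 for GL2, 0.00861 for LEC1 and 0.0306 for ABI3. Among plastid fatty acid synthesis genes it came to 1.74e-08 for ACP5, 2.67e-06 for FAB2, 8.92e-06 for BADC2 and 0.000327 for MCAMT. Among triacylglycerol assembly genes it was 2.05e-07 for DGAT3, 9.55e-06 for ROD1, 0.00337 for FAD3, 0.00424 for FAD2, 0.00439 for FAE1, 0.00485 for DGAT2, 0.00568 for LPCAT2 and 0.00761 for PDAT2. Among suberin, cutin and wax genes the value was 8.34e-07 for GPAT5, 8.84e-07 for FAR1, 1.58e-06 for LACS2, 0.000165 for FAR5, 0.000762 for DCR, 0.00559 for FACT and 0.0319 for BDG1. Among abscisic acid genes it stood at 5.15e-06 for HAI3, 2.8e-05 for HAI2 and 9.67e-05 for HAI1. Among cell division genes it came to 2.19e-05 for KNOLLE, 0.00272 for CYCB1;1, 0.0052 for HINKEL and 0.0408 for PCNA1. Among endosperm genes it was 0.000815 for FWA, 0.000954 for FIS2 and 0.00505 for AGL40. Among jasmonate genes the value was 0.00151 for LOX2, 0.00193 for VSP1, 0.00282 for VSP2 and 0.00904 for AOC3. Of members of other lists it was 7.99e-11 for GPT2, 2.16e-06 for GBSS1, 4.22e-08 for SUS3, 8.28e-05 for SUS2, 3.53e-07 for MLS, 0.000977 for SDP1, 4.27e-06 for DIN10, 3.47e-05 for PDIL1-1 and 0.000507 for SDF2. Further values were 8.2e-05 for BXL1, 0.000328 for MUM4 and 0.000592 for TT10. Outside the lists it was 6.72e-17 for DIR1, 2.24e-16 for AT1G54870, 9.59e-15 for AT3G05260, 2.14e-14 for AT4G11310, 1.87e-13 for AT1G47395, 3.15e-13 for AT5G44550, 3.22e-13 for AT1G21520, 3.35e-12 for RALFL32 and 4.05e-12 for AT3G04190. Further values were 1.23e-11 for AT1G62220, 2.72e-11 for CYP81D6, 3.58e-11 for AT1G78780, 2.5e-10 for BGLU19, 1.36e-09 for MLP28, 5.73e-09 for AT3G02790, 7.27e-09 for AT2G33830, 3.61e-08 for KIN2 and 9.01e-08 for GRP7. Further values after these were 1.3e-07 for AT2G45220, 7.24e-07 for AT4G19240, 0.000152 for AFR, 0.000164 for AT3G30836 and 0.00989 for BG3. The values of DIR1, RALFL32 and ECP31 rest on libraries listed at 0.

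With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and the real grouping was the 1 split with the most calls in each of 7 comparisons. The real and the highest other count were 752 and 6 at 8 DAF, 4246 and 704 at 12 DAF and 7753 and 0 at 16 DAF. They were 12476 and 0 for WT between 8 and 12 DAF, 15534 and 0 for WT between 12 and 16 DAF, and 12224 and 0, then 16031 and 0, for dgat1-1. The 12 DAF split with 704 calls set WT library a with dgat1-1 libraries a and b, a division that follows the share of reads on rDNA. For the average over stages (7104 against at most 4902) and the interaction (6062 against at most 4151), 1 of 100 random relabellings reached the real count, that of the real grouping. That is the smallest share these relabellings allow. It speaks against a chance division of the libraries, but not against anything a whole group shares, such as the hour of harvest.

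Late embryogenesis genes at 16 DAF, all 23 lower with a median of -2.10, were weighed first. The RPKM scaling as the cause is argued against by their median, which stayed at -1.81 under the scaling that brought it nearest to 0. A candidate explanation is an earlier point of development: over the 18851 genes outside the storage, oil body and late embryogenesis lists, the slope of the genotype effect on the WT change from 12 to 16 DAF was -0.2208, -0.2203 and -0.2114 for the 3 divisions of the WT libraries with none on both sides (WT against WT, -0.0086 to 0.0086). That axis was tried after the one fixed beforehand, from 8 to 12 DAF, had given 0.012, so the hypothesis rests on the second axis alone. The WT 16 DAF group is on both sides of the second axis, though no single library is. Anything the libraries of that group share can push the slope below 0 without a delay. The slopes of WT against WT cannot show this, so the second axis does not settle the question. Whether 1 delay was shared by every gene group cannot be told apart from separate changes, since the list's median was -0.609 of its WT change while the other lists that moved by at least 1 in WT ran from -0.729 to -0.010, and an effect of the genotype on these genes without a delay stays untested.

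Clock genes were weighed because GRP7 was among the largest differences at 12 DAF, where all 8 morning genes tested were lower (median -0.84) and 11 of 12 evening genes higher (median 1.18). LHY had 1.74 ± 0.41 RPKM against 10.7 ± 2.40 in WT and FKF1 7.04 ± 0.68 against 1.1 ± 0.38, and the same direction held for 10 of the 20 at 8 DAF and 16 at 16 DAF with 0 called the other way, except GRP8, lower at 16 DAF with median-of-ratios or quantile scaling. For 11 genes the 3 dgat1-1 libraries at 12 DAF all lay outside the WT range of 8 and 12 DAF. That count compared unscaled RPKM between stages, which moves with the rDNA share. WT levels between 8 and 12 DAF were not sampled and may lie outside that range. The count therefore cannot decide on an earlier point of development as the whole cause. At 12 DAF 19 of 20 genes were called in the direction that harvest at a later hour would give. The clock lists and this explanation were chosen after values had been seen, so the count is no test of it. Harvest at another hour cannot be told apart from an effect of the genotype on the clock. The hour was not given, and every library of a group may share it.

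Loci that differed by at least 1 in the same direction at each stage, 9 higher and 3 lower, included 2 transposable element genes, and 4 lay within 0.2 Mb on chromosome 3 (12458560 to 12569997, Araport 11), 2 of which, AT3G00620 and AT3G06095, overlap. Of the 12 loci 1, AT2G15555, lay within 5 Mb of DGAT1. For the other 11 loci this argues against a linked segment of that reach that changes only the genes inside it. An effect of such a segment on genes elsewhere was not tested. At 9 loci all 9 dgat1-1 libraries lay beyond all 9 WT libraries, such as AT3G30836 (9.37 or more against 0.02 or less RPKM). At these loci the dgat1-1 level was thus not seen in WT at any stage sampled. The loci were picked for differing in the same direction at each stage. That choice favours such loci and leaves out many genes that would follow a delay. The count of 9 therefore cannot decide on an earlier point of development. The line background elsewhere in the genome may account for the other 11 loci. It cannot be told apart from an effect of the mutation, because there is 1 allele and no complemented line.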

How the results depend on the processing

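Rescaling to reads outside the rDNA loci and the letter block were chosen after the data were seen, and the other settings before. The counts of called genes at 12 and 16 DAF, averaged over stages and by interaction stayed within 1.5 times under every setting run. The exception was 854 at 12 DAF with only the 2 groups in the model. The main model gives the 6 groups 1 shared spread per gene. The SD of the log2 difference between replicates was 0.150 to 0.163 at 8 DAF and 0.224 to 0.294 at 12 DAF. A shared spread is thus large for 8 DAF and small for 12 DAF, which goes with the 2-group counts of 2739 and 854. A 2-group model also has fewer libraries, and these 2 influences were not separated. The count of 752 at 8 DAF moved to 499 with a pseudocount of 0.1, 1195 with median-of-ratios scaling, 1230 without the top 100 genes, 1281 with quantile normalization, 1339 with rDNA rescaling and 2739 with only the 2 groups. It ran from 497 to 1018 with each library left out. Apart from the 2-group count, the cause of these moves was not tested. Of the 752 genes, 442 kept their call with a pseudocount of 0.1, 692 with median-of-ratios scaling and 733 with rDNA rescaling, and 0 were called the other way. A stable count does not mean that the same genes were called. Of the 4246 genes at 12 DAF, 2899 kept their call with median-of-ratios scaling, 2822 without the top 100 genes and 2911 with quantile normalization. With rDNA rescaling 4134 kept it, and under these scalings 0 were called the other way. With a mean RPKM of at least 5, which tests fewer genes, the counts were 480 at 8 DAF, 7539 and 9748 in WT, and 7280 and 10027 in dgat1-1. Between 12 and 16 DAF in WT, median-of-ratios scaling called 1913 of the 15534 genes in the opposite direction. In dgat1-1 it did so for 2273 of the 16031 genes, and 8548 kept their call.

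The slope on the WT axis at 12 DAF stayed below 0 in all settings, at -0.0443 (pseudocount 0.1), -0.0452 (pseudocount 5), -0.0475 (no filter), -0.0449 (mean RPKM of at least 5), -0.0398 (median-of-ratios), -0.0402 (without the top 100 genes), -0.0391 (quantile) and -0.0418 (rDNA rescaling). With each library left out it ran from -0.0432 to -0.0415. At 8 DAF the slope was 0.0059 (pseudocount 0.1), 0.0033 (no filter), 0.0157 (quantile) and 0.0165 (rDNA rescaling). At 16 DAF it was 0.0183 (pseudocount 0.1), 0.025 (rDNA rescaling) and 0.0209 (without storage, oil body and late embryogenesis genes), and -0.0011 with a mean RPKM of at least 5, the 1 setting that turned its direction. These values moved by more than the SD over the dgat1-1 libraries, and the cause was not tested. At 12 DAF the values with rDNA rescaling and with left-out libraries stayed within the pooled SD of 0.0013.

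No paired analysis was possible because the replicate numbers of the labels match no column. With the letter of the column as a replicate block the counts were 712, 4138 and 7668 at 8, 12 and 16 DAF, and all 33 list calls passed again. The letters gave no sign of pairing: of 9 same-letter pairs 0 had deviations correlated over 0.1 (median r = -0.009), and 4 of 18 libraries correlated best with their own letter. Of the 33 list calls, 30 passed with median-of-ratios scaling, 30 with rDNA rescaling and 2 with an estimated correlation. Mucilage at 12 DAF, not called as tested, passed with both of these scalings. The unfolded protein response at 12 DAF and low-sugar response at 16 DAF were gained with rDNA rescaling. Over 170 comparisons of named genes, left-out libraries aside, a setting ended a call 25 times and gave one 22 times, turned a called direction 0 times and left the call as it was 1964 times. Depth, at 50.1 to 105.8 M reads, limits the low values, which a pseudocount of 0.1 weighs more.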

Other observations

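The gene lists of this part were chosen after values had been seen, so their counts describe these libraries and are no independent test. Genes of aliphatic glucosinolate synthesis, which make methionine-derived defence compounds, were lower in dgat1-1 at each stage. Of 15 tested, 9 were lower at 8 DAF, 13 at 12 DAF and 13 at 16 DAF with 0 higher (limma, Benjamini-Hochberg), and the medians were -0.52, -0.63 and -1.18. Under the other scalings 9 to 14 were lower, and at 16 DAF BCAT3 was higher without the top 100 genes or with rDNA rescaling. At 16 DAF MAM1 (AT5G23010), which lengthens the methionine chain, had 3.91 ± 0.24 RPKM against 17.1 ± 1.41 (-1.89), and BCAT4 (AT3G19710) had 5.34 ± 0.63 against 20.8 ± 2.54 (-1.78). CYP79F1 (AT1G16410) had 1.97 ± 0.17 against 7.29 ± 0.54 (-1.48) and MYB28 (AT5G61420), a regulator of the pathway, 1.74 ± 0.22 against 5.21 ± 0.45 (-1.18). Of the indole branch 2 of 7 genes were expressed enough to test, and 1, UGT74B1, was called lower at 16 DAF, a call that ended with rDNA rescaling. At 12 DAF 0 were called, but 1 or 2 were lower with the other scalings.

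Genes that respond to low iron were higher in dgat1-1 at 16 DAF. Of 8 tested, 6 were higher and 1 lower there (median 0.86), and at 8 and 12 DAF 0 were called. Under the other scalings the same count was higher at 16 DAF and 1 or 2 lower, and at 12 DAF 1, OPT3, was lower. The peptide genes IMA1 (AT1G47400), IMA2 (AT1G47395) and IMA3 (AT2G30766), known to promote iron uptake, had 3.25 ± 1.16, 16.2 ± 2.44 and 8.44 ± 0.87 RPKM against 0.01 ± 0.02, 0.14 ± 0.02 and 0.12 ± 0.02 in WT. The transporter OPT3 (AT4G16370) had 31.5 ± 1.67 against 19.7 ± 1.24 (0.65), and FRO3 and ORG1 were higher too, while the regulator PYE (AT3G47640) was lower, at 16.7 ± 1.65 against 32.7 ± 1.19 (-0.93). Of 7 iron storage genes 4 were lower at 16 DAF (FER1, FER2, FER4 and AT1G76800) and 1 higher (AT1G21140), with the seed ferritin FER2 (AT3G11050) at 46.5 ± 3.90 against 121.9 ± 0.35 (-1.38) and FER1 (AT5G01600) at 6.01 ± 1.33 against 12.7 ± 1.37 (-0.98). With rDNA rescaling FER3 and VIT1 were higher as well, and VIT1 also without the top 100 genes. At 12 DAF VIT1 and AT1G21140 were higher and 0 were lower. With the other scalings VIT1 was still higher there and 1 or 2 of FER2 and FER4 were lower.

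AT3G12510 was listed at 0 in the 3 dgat1-1 libraries of 16 DAF and at 5.72 to 24.7 RPKM in the other 15 libraries, which can mean a failed estimate.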
